A study of Mus musculus with 8 samples.

How the data were processed

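RNA from dorsal pancreatic epithelium of mouse embryos at embryonic day 12.5 was measured on 8 single-colour Agilent whole-genome arrays. The 4 Sox9 mutant arrays came from embryos with floxed Sox9 alleles and a Pdx1-Cre transgene, which deletes Sox9 in the developing pancreas, and the 4 wild-type arrays came from embryos with the same floxed alleles and no Cre. Per the labels, each RNA was pooled from 3 embryos and 250 ng was labelled. The series description speaks of fewer biological replicates than the 4 arrays per genotype that were deposited. All 8 arrays were kept. No 2 arrays of a genotype held identical values, which excludes repeated files but not repeat hybridizations of 1 pool, so that n = 4 rests on the labels. Genotype and the presence of Cre are the same split of the samples and cannot be separated. Y-linked genes were low in 3 of 4 wild-type pools and in no mutant pool, so that embryo sex ran in part with genotype. The arrays lay on 3 slides: slide 1 held wild-type replicate 2 and mutant replicate 3, slide 2 held wild-type replicate 3 and mutant replicates 1 and 4, and slide 3 held wild-type replicates 1 and 4 and mutant replicate 2.

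Per the file headers, the authors' scanner files were made with Agilent Feature Extraction 9.5.3.1. Their deposited processed signal is an intensity on a linear scale, background subtracted and detrended within each array, with substituted values for dim spots and no normalization between arrays. The deposited mean signal and local background are intensity values as scanned. The deposited control type and quality columns are flags of each spot, which count as other than a measurement. The deposited value table of the authors also holds intensity values on a linear scale, with 33067 features, no control spots and a median of 227 in every array. Its values are quantile normalized as the equal distributions show, and their ranks follow the mean signal of the scanner files with a rank correlation of at least 0.999 on each array. The submitters' notes name limma without a version or steps, so the background method and the rule by which dim spots were removed from that table stay unknown. The values are not centred and are not ratios, so each has no direction of its own.

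The analysis started from the processed signal. Each array file held 45018 spots, of which 1639 were control spots and were left out. Spots marked by the scanner software as non-uniform or as population outliers were left out, which left 9 genes with a missing value. Log2 signals were taken, the 75th percentile of each array was subtracted, and the spots of a probe were averaged. A log2 value of 0 is therefore the 75th percentile of that array's signal. Of 41174 probes, 27389 were kept because they were marked well above background on at least 4 of the 8 arrays. Gene names came from RefSeq accessions for 23374 probes, from another probe of the same name for 4500, and from the name in the file for 13300. Each gene was represented by its kept probe with the highest mean signal, giving 18506 genes for testing out of 27828 names on the array. Of these genes, 6334 had more than 1 kept probe. Probe positions are those of the scanner files on mouse assembly mm8. No genome or annotation was used here to place probes in exons.

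The 75th percentile of the processed signal was 372, 620, 526 and 640 in wild-type replicates 1 to 4 and 615, 522, 413 and 624 in mutant replicates 1 to 4. The share of spots well above background was 62.4%, 65.1%, 77.7% and 66.9% in the wild-type arrays and 75.3%, 65.8%, 59.4% and 67.5% in the mutant arrays. The number of arrays, 4 per genotype, limits the precision.

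Mutant and wild-type arrays were compared gene by gene with a linear model and moderated statistics (lmFit and eBayes, limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Single values were compared with a two-sided exact permutation test over the 70 assignments of 4 against 4 arrays, whose smallest possible p is 0.0286. Before the data were examined, 25 gene lists with 499 entries were fixed from textbook knowledge of the tissue, of Sox9 and of cell types the dissected tissue could hold. Of these, 24 were tested as sets, and the list of sex-linked genes was kept for values only. Shifts of the lists against all other genes were tested with camera (limma) at a preset correlation of 0.01, with adjustment over the 24 lists, and again with an estimated correlation and with fry, which does not compare a list with other genes. Members of each list were also counted with p adjusted over the list alone. Other tools were Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and the R package data.table, version 1.17.8.

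The rule for the genes named was also set before the data were examined. It takes Sox9, then the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups did not overlap and whose symbols are official-looking, with members of near-identical families named as uncertain. It adds up to 4 members of each list past the threshold with the largest change, or the 2 members of smallest p where none passed, and the sex-linked genes as values. There were 808 genes eligible for the largest changes, 269 higher and 539 lower. A gene named by 2 parts of the rule counts under both. Values of 4 genes that the rule names are not reported here, and these genes stay in all counts.

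The method was tested on simulated data with 18506 genes and the same 4 against 4 design, in which 50 genes were changed at each of 4 sizes. It recovered 6% of changes of 0.5 on the log2 scale, 56% of changes of 1, 84% of changes of 2 and 96% of changes of 3. Of 132 genes called, 11 had not been changed, or 8.33%. Genes were simulated independently of each other, without slide effects and with few genes changed, so these rates need not hold for the arrays.

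Alternatives set before the data were examined were quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter requiring all 8 arrays, outlier spots kept, the mean of a gene's probes, slide as a fixed or a random block, the replicate number as a block, a variance trend with robust moderation, array weights, adjusted p thresholds of 0.01 and 0.1, a 2-fold minimum, and leaving out each array in turn. Alternatives added after the data were seen were the other Sox9 probes, leaving out the 2 arrays of lowest weight together, leaving out the 2 mutant arrays of highest liver gene levels together, and the level of Y-linked genes as a covariate.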

Results

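Gene expression was measured in dorsal pancreatic epithelium at e12.5 from 4 wild-type and 4 Sox9 mutant samples, each a pool from 3 embryos on an array of its own. At this stage the pancreatic epithelium holds progenitors of the acinar, ductal and endocrine lineages. The single comparison, mutant against wild-type, addresses which genes and pathways depend on Sox9, a transcription factor of pancreatic progenitors, in the early pancreas. Between 59.4% and 77.7% of spots lay well above background on each array. The first principal component held 34.2% of the variance and separated the genotypes, with the wild-type arrays between -49.5 and -15.1 and the mutant arrays between 15.7 and 54.0. The second held 23.6% and ran in part with slide. On it the arrays of slide 3 lay between 19.7 and 39.1, those of slide 1 at -2.23 and -2.97, and those of slide 2 between -62.5 and -1.07. The main fit had no slide term, and the correlation of arrays on a slide was estimated at 0.194.

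Sox9 itself fell in the mutant samples and stayed detectable there. Its probe of highest signal, at bases 112603585 to 112603644 of chromosome 11 (mm8), had log2 signals of 3.01, 2.13, 1.82 and 2.19 in wild-type replicates 1 to 4 and of -0.61, -1.79, -0.0057 and 0.77 in mutant replicates 1 to 4. The mean was 2.29 ± 0.51 (SD, n = 4) in wild-type and -0.41 ± 1.08 (SD, n = 4) in mutant samples. The log2 difference was -2.70 (SE 0.517, adjusted p = 0.0253 in limma), which is 6.49-fold lower, and the exact permutation p was 0.0286, the smallest that 4 against 4 arrays can give. A probe at bases 112601784 to 112601843 gave -3.27 (adjusted p = 0.0231, 9.65-fold lower). A dimmer probe, whose listed position runs over 853 bases from 112599086 to 112599938, gave -1.44 and did not pass the threshold (adjusted p = 0.0748 in limma). The exact permutation p was 0.0286 for each of these 2 probes as well. Within slides 1, 2 and 3 the difference was -2.14, -1.74 and -4.39, and with slide as a block it was -2.81 (adjusted p = 0.0435). The call was lost on leaving out wild-type replicate 1 (-2.46, adjusted p = 0.0672), wild-type replicate 2 (-2.75, 0.0525), wild-type replicate 4 (-2.73, 0.0691) or mutant replicate 1 (-2.63, 0.0732), and over all alternatives the adjusted p ran from 0.00510 to 0.260. General epithelial genes fell in the same 4 samples, with a median of -2.13 (Cldn3 -2.75, Cdh1 -2.51). The size of the Sox9 fall therefore does not separate deletion of the gene from a smaller share of epithelium.

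**Figure D1:**
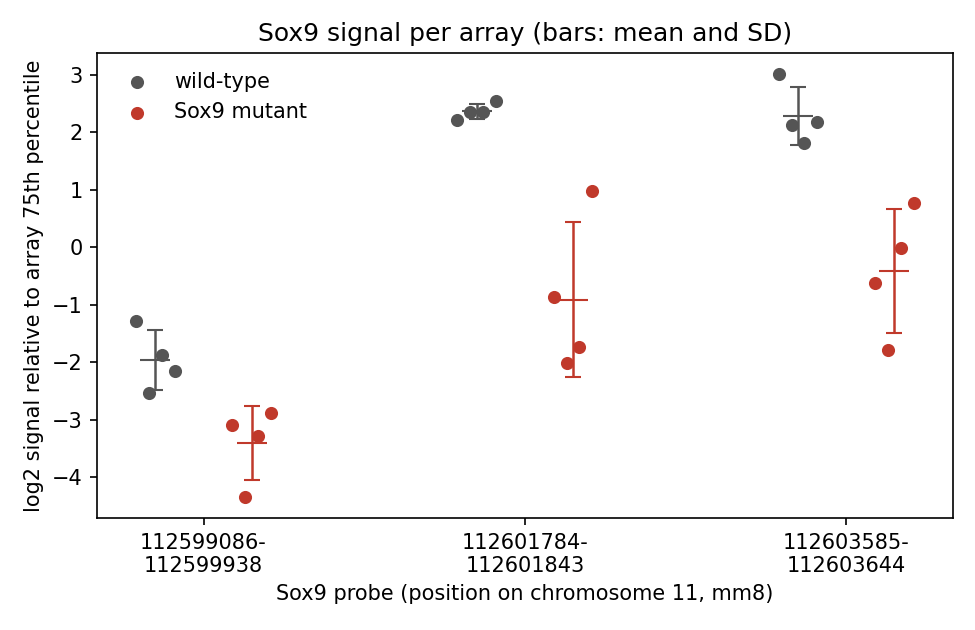
Log2 Sox9 signal relative to the 75th percentile of the array (vertical axis) for the 3 Sox9 probes, named by position on chromosome 11 (horizontal axis), with 1 point per array, wild-type in grey and Sox9 mutant in red, and bars for the mean and SD of 4 arrays. At bases 112603585 to 112603644 the wild-type arrays lie between 1.82 and 3.01 and the mutant arrays between -1.79 and 0.77.

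The Sox9 mutant samples had lower levels of many pancreatic transcription factors, of endocrine and acinar genes and of general epithelial genes. The design does not separate a smaller share of epithelium from lower expression within it. Most measured genes of mesenchyme, mesothelium, endothelium and macrophages had a log2 difference above 0, and fewer passed the threshold. Past the threshold were 4 of 22 mesenchyme, 2 of 12 mesothelium, 2 of 20 endothelium and 5 of 19 macrophage genes, and with an estimated correlation no list passed in camera (lowest adjusted p 0.109). The largest falls were in Nepn, an extracellular matrix proteoglycan (30.6-fold), and in Spp1, the secreted phosphoprotein osteopontin (28.3-fold), an order that depended on the background treatment, since in the authors' table Spp1 gave -4.68, Nkx6-1 -3.47, Mia -3.39, Clps -3.36, Tmem171 -3.06 and Nepn -3.05. The largest rise was in Akr1b7, an aldo-keto reductase (51.1-fold), and the plasma protein genes Alb, Afp and Itih2 also rose. Cell cycle genes showed no member past the threshold. In limma, 994 of 18506 genes passed the threshold, 288 higher and 706 lower in the mutant, so that 29.0% of the changed genes were higher. At least 2-fold changes were found in 45 higher and 489 lower genes, and the median log2 difference of all genes was 0.016. In the authors' value table, 1311 genes passed, 557 higher and 754 lower, so that 42.5% were higher there. The groups did not overlap for any of the 994 genes, and this alone puts each of them in the same direction within every slide. With slide as a block, 1292 genes passed, 431 higher and 861 lower. The count fell to 503, 656, 494 and 395 on leaving out wild-type replicates 1, 2, 3 and 4, and to 412 and 448 on leaving out mutant replicates 1 and 2. It was 419 with no filter on dim probes and 340 with the replicate number as a block, but 1529 with slide as a random block and 1709 with array weights. Without mutant replicates 1 and 2 together 0 genes passed, and with the Y-linked level, which runs with genotype, as a covariate 2 passed. Fold changes of dim genes depended on how background was treated. Of the 87 named genes past the threshold besides Sox9, 25 had a log2 difference at least 1.5 times smaller in the authors' table and 28 with normexp background correction, in the same direction. Of 289 changed genes with more than 1 kept probe, 11 had a probe in the opposite direction, and for Tanc2 alone, named after its values were seen, that probe passed the threshold.

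The 12 largest falls included genes of secreted proteins, enzymes and transcription factors. Tmem171, which encodes a transmembrane protein, fell by 4.45 on the log2 scale (SE 0.708, adjusted p = 0.0131, 21.9-fold). Mia, a secreted protein known from cartilage and melanoma, fell by 4.19 (SE 0.525, adjusted p = 0.00813, 18.3-fold). Slc28a3, a nucleoside transporter, fell by 3.77 (SE 0.589, adjusted p = 0.0126). The flavin monooxygenase Fmo2 fell by 3.86, and the sodium pump regulator Fxyd2 fell by 3.83. The epithelial transcription factor Elf5 fell by 3.63, the NADPH oxidase activator Noxa1 fell by 3.53, and the sphingolipid enzyme Degs2 fell by 3.53. Pax4 and Nkx6-1, described with their lists, complete the 12. Nepn fell by 4.94 (SE 0.861, adjusted p = 0.0182) and Spp1 fell by 4.82 (SE 0.854, adjusted p = 0.0193). In the mutant samples, Nepn, Tmem171 and Noxa1 were above background on 3 of 4 arrays, Fmo2, Pax4 and Elf5 on 2, and Fxyd2 and Degs2 on 1. In the authors' table the log2 difference was -3.05 for Nepn, -2.0 for Fmo2, -1.33 for Fxyd2, -1.70 for Elf5 and -1.13 for Degs2, and with normexp it was -2.86 for Tmem171 and -2.25 for Noxa1. Of these 12 genes, 7 passed the threshold on leaving out any of the 8 arrays, and the highest adjusted p among the other 5 was 0.0751.

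The 12 largest rises included several genes of plasma proteins. Akr1b7 rose from a mean of -5.06 ± 0.54 (SD, n = 4) to 0.62 ± 0.32 (SD, n = 4), a log2 difference of 5.68 (SE 0.281, adjusted p = 0.000486 in limma), and was above background on 2 of 4 wild-type arrays. In the authors' table the difference was 3.53 for Akr1b7, 1.51 for Calb1 and 1.16 for F12. Calb1, the calcium-binding protein calbindin, rose by 2.74 (SE 0.261, adjusted p = 0.00726, 6.69-fold) and was above background on 3 of 4 wild-type arrays. Onecut2, a transcription factor of liver and pancreas, rose by 1.83 (SE 0.229, adjusted p = 0.00813, 3.57-fold). The coagulation factor F12 rose by 2.08, and Cpa3, a mast cell carboxypeptidase, rose by 1.75. Pzp, a protease inhibitor of plasma, was above background on no wild-type array and was at least 3.42-fold higher in the mutant, and it did not pass in the authors' table (0.61, adjusted p = 0.0659) or with normexp (0.48, adjusted p = 0.277), within a range of 0.0166 to 0.282 over the alternatives. Csta1 (2.29) and Serpina3g (1.83) belong to families of near-identical genes, so which member was measured is uncertain. Alb, Itih2 and Afp, described with the liver genes, were also among the 12. Akr1b7, Calb1, Itih2, Afp and Onecut2 passed the threshold on leaving out any of the 8 arrays, and the highest adjusted p among the other 7 was 0.131.

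Many pancreatic progenitor and endocrine transcription factors fell. Of 18 measured progenitor factors, 11 fell, none rose and 7 did not pass (13 fell when adjusted over the list alone). The median log2 difference was -2.07 (camera adjusted p = 7.56e-13, and adjusted p = 0.109 with an estimated correlation). Within slides 1, 2 and 3 the mean shift was -1.48, -1.40 and -2.36, and with slide as a block it was -1.77. Nkx6-1, needed for beta cells, fell by 3.66 (SE 0.516, adjusted p = 0.00961, 12.6-fold). Pdx1, needed for the formation of the pancreas, fell by 3.08 (SE 0.492, adjusted p = 0.0132, 8.44-fold). Nkx2-2 fell by 3.03 and Mnx1 fell by 2.93, with Mnx1 above background on 2 of 4 mutant arrays. Of 19 measured endocrine progenitor and islet factors, 8 fell, none rose and 11 did not pass (12 fell when adjusted over the list alone). Their median was -1.29 (camera adjusted p = 1.89e-09, and adjusted p = 0.109 with an estimated correlation) and ran from -1.63 to -0.60 over the alternatives. Their mean shift within slides was -1.08, -0.85 and -1.91, and -1.30 with slide as a block. Neurog3, the factor that starts endocrine differentiation, fell by 2.68 (SE 0.227, adjusted p = 0.00522, 6.43-fold). Pax4, a factor of beta cell development, fell by 3.82 (SE 0.392, adjusted p = 0.00810, 14.1-fold), and Insm1 fell by 2.59. Pax4 and Insm1 were above background on 2 of 4 mutant arrays each, and the authors' table gave -2.15 for Pax4, -1.07 for Insm1 and -1.60 for Mnx1.

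Several islet hormone, acinar and duct genes fell as well. Of 20 hormone and granule genes, 10 fell, none rose and 10 did not pass (18 fell when adjusted over the list alone). The median was -0.89 (camera adjusted p = 7.70e-15, and adjusted p = 0.109 with an estimated correlation), the mean shift within slides was -0.95, -0.84 and -1.30, and with slide as a block it was -1.04. The hormone genes Gast and Ppy fell by 1.97 and fell by 1.54, Chgb, a granule protein, fell by 1.97, and the prohormone convertase Pcsk1 fell by 1.67. The authors' table gave -1.02 for Gast and -1.09 for Pcsk1, and -1.94 for the acinar gene Cela1 and -1.39 for the cilium gene Pkhd1. Of 15 acinar genes, 9 fell, none rose and 6 did not pass (11 fell and 1 rose when adjusted over the list alone). Their median was -1.95 (camera adjusted p = 1.33e-08, and adjusted p = 0.117 with an estimated correlation), and their mean shift within slides was -1.68, -1.14 and -2.61, with -1.82 for slide as a block. Clps, the colipase of pancreatic juice, fell by 3.53 (SE 0.478, adjusted p = 0.00917, 11.5-fold). Cela1, an elastase above background on 3 of 4 mutant arrays, fell by 3.11, and Rbpjl, a subunit of the acinar transcription factor complex, fell by 3.05. Of 19 duct and primary cilium genes, 6 fell, 1 rose and 12 did not pass (8 fell and 1 rose when adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.0208, and adjusted p = 0.109 with an estimated correlation), and their mean shift within slides was -0.65, -0.47 and -0.90, with -0.68 for slide as a block. Spp1 and Pkhd1, the gene of recessive polycystic kidney disease (-2.88, above background on 2 of 4 mutant arrays), fell, while Onecut2 rose. In some fit that left out 1 array, Cela1, Rbpjl and Spp1 lost the call (highest adjusted p 0.0632, 0.0972 and 0.0612).

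General epithelial genes showed the lowest list median in the main fit, an order that did not hold in every setting. Over the alternatives their median rose to as much as -1.58, while that of acinar genes was -1.65 at most. Of 24 measured, 22 fell, none rose and 2 did not pass (23 fell when adjusted over the list alone). The median was -2.13 (camera adjusted p = 1.93e-26 at the preset correlation of 0.01, and adjusted p = 0.109 with an estimated correlation, here 0.616). The smaller p thus treats genes that moved together as nearly independent. The mean shift within slides was -1.92, -1.53 and -2.54, and -2.0 with slide as a block. Cldn3, a tight junction claudin, fell by 2.75 (SE 0.359, adjusted p = 0.00880, 6.73-fold), and Cdh1, which encodes E-cadherin, fell by 2.51 (SE 0.409, adjusted p = 0.0140, 5.70-fold). Esrp1, an epithelial splicing regulator above background on 3 of 4 mutant arrays, fell by 2.50, and the transcription factor Elf3, above background on 2, fell by 2.48. The authors' table gave -1.37 for Esrp1 and -1.19 for Elf3, and Esrp1 lost the call in 6 of the 8 fits that left out 1 array. The progenitor, endocrine, hormone, acinar, duct and cartilage target lists fell in the same 4 samples as this list.

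Most markers of other cell types in or around the pancreas had a log2 difference above 0, and most did not pass the threshold. Above 0 were 21 of 22 mesenchyme, 11 of 12 mesothelium, 20 of 20 endothelium and 19 of 19 macrophage genes. In the simulated data 6% of changes of 0.5 were recovered, so many changes of about this size would go uncalled. Of 22 mesenchyme genes, 4 rose, none fell and 18 did not pass (13 rose when adjusted over the list alone), with a median of 0.56 (camera adjusted p = 4.27e-09, and adjusted p = 0.109 with an estimated correlation). Bapx1, the mesenchymal factor Nkx3-2, rose by 0.91 and the growth factor receptor Pdgfra rose by 0.80, with the matrix genes Postn (0.73) and Col1a2 (0.67). With the mean of its probes Col1a2 gave 0.17 (adjusted p = 0.884), the highest adjusted p over its alternatives, and the lowest was 0.0202. Of 12 mesothelium genes, 2 rose, none fell and 10 did not pass (9 rose and 1 fell when adjusted over the list alone), with a median of 0.71 (camera adjusted p = 1.99e-05, and adjusted p = 0.109 with an estimated correlation). These were Bnc1 (0.94) and Upk1b (0.63). Of 20 endothelium genes, 2 rose, none fell and 18 did not pass (11 rose when adjusted over the list alone), with a median of 0.41 (camera adjusted p = 1.61e-08, and adjusted p = 0.109 with an estimated correlation). These were Emcn (0.67) and Eng (0.54). Of 19 macrophage and leukocyte genes, 5 rose, none fell and 14 did not pass (19 rose when adjusted over the list alone), with a median of 0.63 (camera adjusted p = 1.18e-12, and adjusted p = 0.109 with an estimated correlation). Adgre1, the F4/80 antigen, rose by 0.87 and Csf1r, the receptor for colony-stimulating factor, rose by 0.81, with Fcer1g (0.66) and the complement gene C1qc (0.64). Of the genes named here for these 4 cell types, only Bapx1 passed on leaving out any of the 8 arrays, and the highest adjusted p was 0.124 for mesenchyme, 0.0973 for mesothelium, 0.117 for endothelium and 0.121 for macrophage genes. No erythroid gene of 18 passed, although the list shifted by a median of 0.44 (camera adjusted p = 0.000651, and adjusted p = 0.173 with an estimated correlation). Epor had a difference of 0.62 (adjusted p = 0.0598) and Tal1 of 0.40 (adjusted p = 0.0922). The mean shifts within slides 1, 2 and 3 were 0.69, 0.42 and 0.60 for mesenchyme, 0.41, 0.56 and 0.78 for mesothelium, 0.54, 0.32 and 0.48 for endothelium, 0.79, 0.56 and 0.75 for macrophages, and 0.48, 0.25 and 0.69 for erythroid genes. With slide as a block they were 0.56, 0.60, 0.44, 0.69 and 0.48.

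Several neural crest and peripheral neuron genes fell. Of 15 measured, 4 fell, none rose and 11 did not pass (6 fell and 1 rose when adjusted over the list alone), with a median of -0.53 (camera adjusted p = 0.000276, and adjusted p = 0.117 with an estimated correlation). Over the alternatives the median ran from -1.04 to -0.22. Sox10, a factor of the neural crest and glia, fell by 1.54 (SE 0.248, adjusted p = 0.0137). Th, the first enzyme of catecholamine synthesis, fell by 1.41, and Foxd3, a factor of early neural crest, fell by 0.99. The authors' table gave -0.66 for Th and -0.43 for Foxd3, which did not pass there (adjusted p = 0.176, within a range of 0.0277 to 0.220), and Foxd3 lost the call in 7 of the 8 fits that left out 1 array. The mean shift within slides was -1.03, -0.66 and -0.17, and -0.59 with slide as a block.

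**Figure D2:**
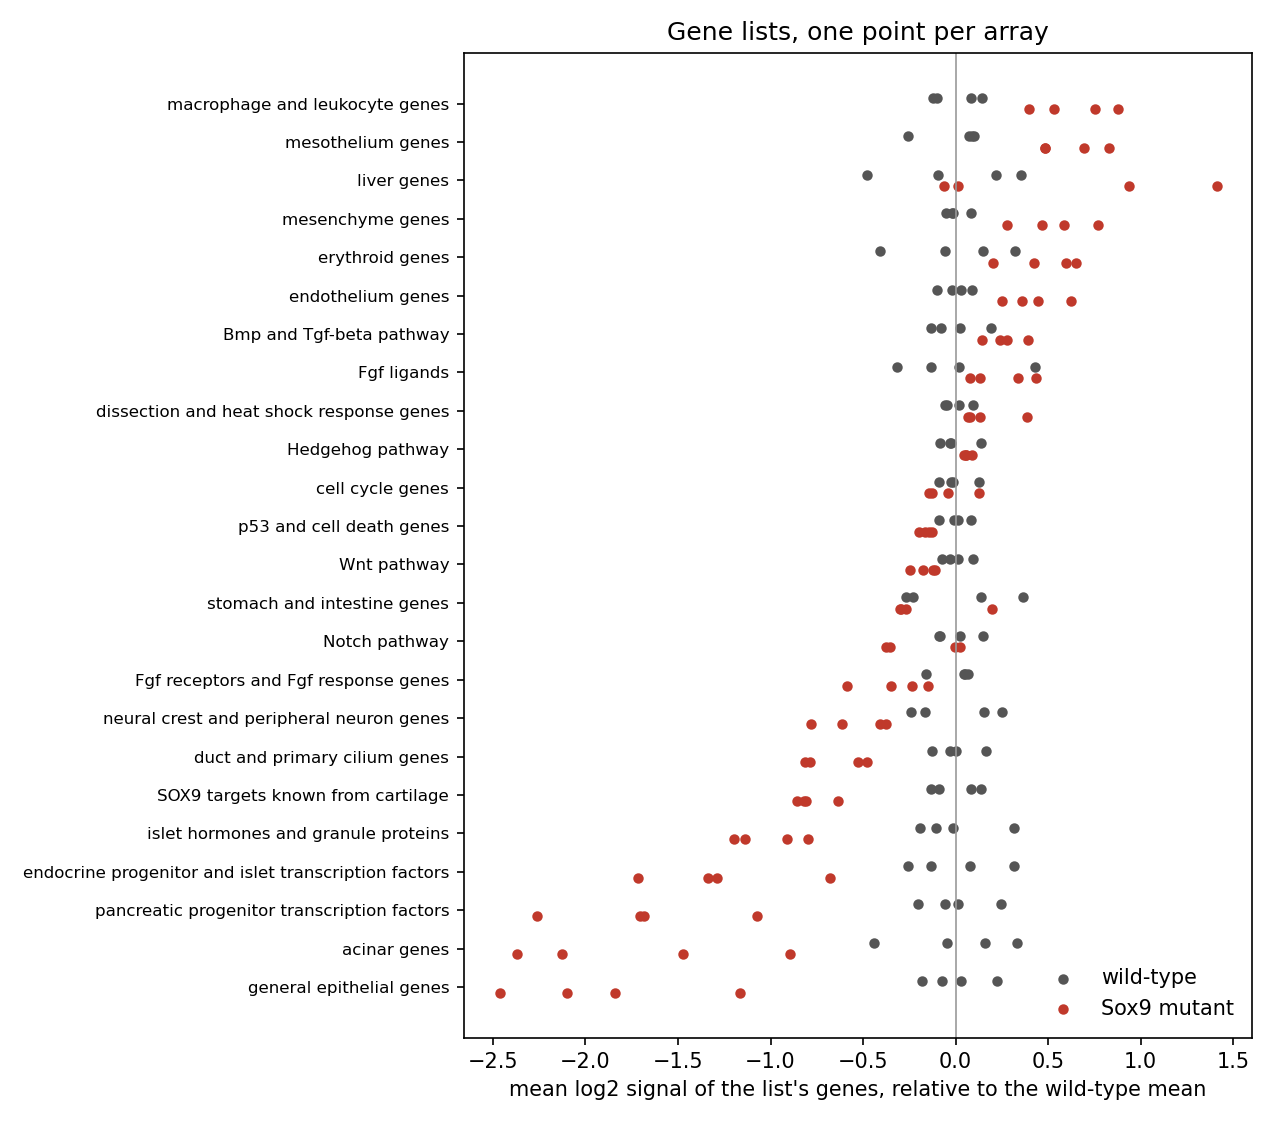
Mean log2 signal of the measured genes of each of the 24 lists (horizontal axis, relative to the mean of the 4 wild-type arrays) by list (vertical axis), with 1 point per array, wild-type in grey and Sox9 mutant in red. All mutant arrays lie below all wild-type arrays for general epithelial genes (median of members -2.13) and above them for macrophage and leukocyte genes (median of members 0.63).

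Genes known as SOX9 targets in cartilage included several that fell. Of 13 measured, 5 fell, none rose and 8 did not pass, with the same 5 falling when adjusted over the list alone. The median was -0.30 (camera adjusted p = 0.000607, and adjusted p = 0.109 with an estimated correlation). Col9a1 fell by 2.58 (SE 0.233, adjusted p = 0.00645, 5.99-fold) and Acan, the cartilage proteoglycan aggrecan, fell by 2.08 (SE 0.296, adjusted p = 0.00979, 4.22-fold). The collagen genes Col9a3 and Col11a2 fell by 2.41 and fell by 2.07, and Col9a3 lost the call in 7 of the 8 fits that left out 1 array. General epithelial genes fell in the same 4 samples, with a median of -2.13. Col9a3 gave -1.60 in the authors' table, and Col11a2 gave -1.09 and did not pass with the mean of its probes (adjusted p = 0.0549, within a range of 0.00213 to 0.113). Within slides the mean shift was -0.69, -0.66 and -0.92, and -0.76 with slide as a block.

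Several receptors and a co-receptor of the Fgf pathway fell. Fgfr4 fell by 2.72 (SE 0.359, adjusted p = 0.00881, 6.58-fold), Klb, a co-receptor of Fgfr4, fell by 2.20 (SE 0.316, adjusted p = 0.00991, 4.60-fold), and Fgfr2, the receptor of Fgf7 and Fgf10, fell by 1.40 (SE 0.195, adjusted p = 0.00958, 2.63-fold). Fgfrl1, a receptor without a kinase domain, fell by 0.74 and lost the call in 3 of the 8 fits that left out 1 array. General epithelial genes, with a median of -2.13, fell in the same 4 samples as these genes. With the mean of its probes Fgfr4 gave -1.80. Fgfr1 (0.46, adjusted p = 0.177) and Fgfr3 (-0.15, adjusted p = 0.882), named after their values were seen, did not pass in limma. Of 20 Fgf receptor and response genes, 5 fell, none rose and 15 did not pass (7 fell when adjusted over the list alone). The median was -0.075 (camera adjusted p = 0.0327, and adjusted p = 0.300 with an estimated correlation), and the mean shift within slides was -0.31, -0.30 and -0.53, with -0.38 for slide as a block. This call was lost with slide as a block (adjusted p = 0.0509) and on leaving out wild-type replicate 2 (0.143), mutant replicate 1 (0.0556) or mutant replicate 2 (0.188), within a range of 0.00398 to 0.447 over the alternatives. Of 13 Fgf ligands, 1 rose, none fell and 12 did not pass, with the same count when adjusted over the list alone. Their median was 0.32 (camera adjusted p = 0.0379, and adjusted p = 0.244 with an estimated correlation). The gene that rose was Fgf13 (0.73), which did not pass in the authors' table (0.40, adjusted p = 0.132, within a range of 0.0180 to 0.286), and the mean shift within slides was 0.45, -0.18 and 0.39, with 0.20 for slide as a block. The ligand call was lost with slide as a block (adjusted p = 0.161) and on leaving out wild-type replicate 2 (0.143) or 4 (0.0702) or mutant replicate 1 (0.0855) or 2 (0.0764), within a range of 0.00234 to 0.954.

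Hedgehog and Bmp pathway genes changed in both directions. Of 14 Hedgehog genes, 4 rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone. The median was 0.33 (camera adjusted p = 0.0236, and adjusted p = 0.109 with an estimated correlation). Hhip, a membrane antagonist of Hedgehog ligands, fell by 2.77 (SE 0.409, adjusted p = 0.0107) and was above background on 1 of 4 mutant arrays. Its difference was -0.80 in the authors' table. The co-receptors Boc and Gas1 rose by 0.77 and by 0.72, and the transcription factor Gli3 rose by 0.62. These 3 lost the call in 7, 6 and 7 of the 8 fits that left out 1 array, and with the mean of its probes Gli3 gave 0.43 and did not pass (adjusted p = 0.190, within a range of 0.0174 to 0.254). Mesenchyme genes, with a median of 0.56, were higher in the same samples. Within slides the Hedgehog list shifted on average by 0.081, -0.071 and 0.11, and 0.036 with slide as a block. Of 22 Bmp and Tgf-beta genes, 1 rose, 1 fell and 20 did not pass (3 rose and 1 fell when adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00755, and adjusted p = 0.117 with an estimated correlation). The ligand Bmp6 rose by 1.0 (SE 0.127, adjusted p = 0.00840) and the ligand Bmp7 fell by 1.34 (SE 0.226, adjusted p = 0.0162). With the mean of its probes Bmp6 gave 0.61 and did not pass (adjusted p = 0.182, within a range of 0.00332 to 0.182). The mean shift within slides was 0.52, 0.00028 and 0.31, and 0.25 with slide as a block.

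Other lists did not shift past the threshold. Of 20 liver genes, 3 rose, 3 fell and 14 did not pass (3 rose and 4 fell when adjusted over the list alone), with a median of 0.26 (camera adjusted p = 0.478). Alb, serum albumin, rose by 3.48 (SE 0.652, adjusted p = 0.0233, 11.1-fold), the plasma protein gene Itih2 rose by 2.60 (SE 0.202, adjusted p = 0.00412, 6.07-fold), and Afp, alpha-fetoprotein, rose by 2.23 (SE 0.278, adjusted p = 0.00813, 4.70-fold). Ambp, another plasma protein gene, fell by 1.59. The mean shift of liver genes within slides was 0.41, 0.12 and 1.35, and 0.65 with slide as a block. The log2 difference of Ahsg, another liver gene, was 2.56 (adjusted p = 0.20), with a rise above the wild-type mean mostly in mutant replicates 1 and 2. Of 20 Notch genes, 3 fell, none rose and 17 did not pass, with the same count when adjusted over the list alone, and the median was -0.068 (camera adjusted p = 0.233). The ligands Dll3 and Dll1 fell by 1.49 and fell by 1.10, and Nrarp, a target of Notch signalling, fell by 0.96, and each lost the call in 7 of the 8 fits that left out 1 array (highest adjusted p 0.0945, 0.112 and 0.125). Of 22 Wnt genes, 2 fell, none rose and 20 did not pass, with the same count when adjusted over the list alone. Their median was 0.12 while their mean was -0.17 and the camera direction was down (adjusted p = 0.755). Wnt7b fell by 1.77 and Rnf43, a membrane inhibitor of Wnt signalling, fell by 1.65, and Wnt7b lost the call in 4 of these 8 fits.

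None of 28 cell cycle genes passed, over all genes or over the list alone, and the median was -0.045 (camera adjusted p = 0.386). Of these, Ccne2 had a difference of -0.33 (adjusted p = 0.268) and Ccnb1 of -0.27 (adjusted p = 0.399). Of 18 p53 and cell death genes, 1 rose, 3 fell and 14 did not pass (2 rose and 5 fell when adjusted over the list alone), with a median of -0.024 (camera adjusted p = 0.397). Cdkn1a, an inhibitor of the cell cycle, fell by 1.92 (SE 0.213, adjusted p = 0.00813), Perp fell by 0.98, Gadd45a fell by 0.65 and the death receptor Fas rose by 0.54. Perp, Gadd45a and Fas lost the call in 4, 5 and 8 of the 8 fits that left out 1 array. Fas did not pass with normexp (0.35, adjusted p = 0.122, within a range of 0.0207 to 0.363). The mean shift within slides was 0.086, -0.078 and -0.47 for Notch, -0.049, -0.24 and -0.24 for Wnt, 0.14, -0.067 and -0.15 for cell cycle and -0.19, -0.048 and -0.21 for p53 genes, and with slide as a block -0.17, -0.19, -0.040 and -0.15. With an estimated correlation, no list of the 24 passed in camera, and the smallest adjusted p was 0.109, while 11 had an unadjusted p under 0.05. The estimate ran from -0.034 for the Hedgehog list to 0.616 for the general epithelial list, against the preset 0.01. In fry, which tests whether the genes of a list move one way on balance, 17 lists passed. Of these, 16 also passed in camera, while the p53 list passed in fry only (adjusted p = 0.0141) and the Fgf ligand list did not pass in fry (0.165).

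**Figure D3:**
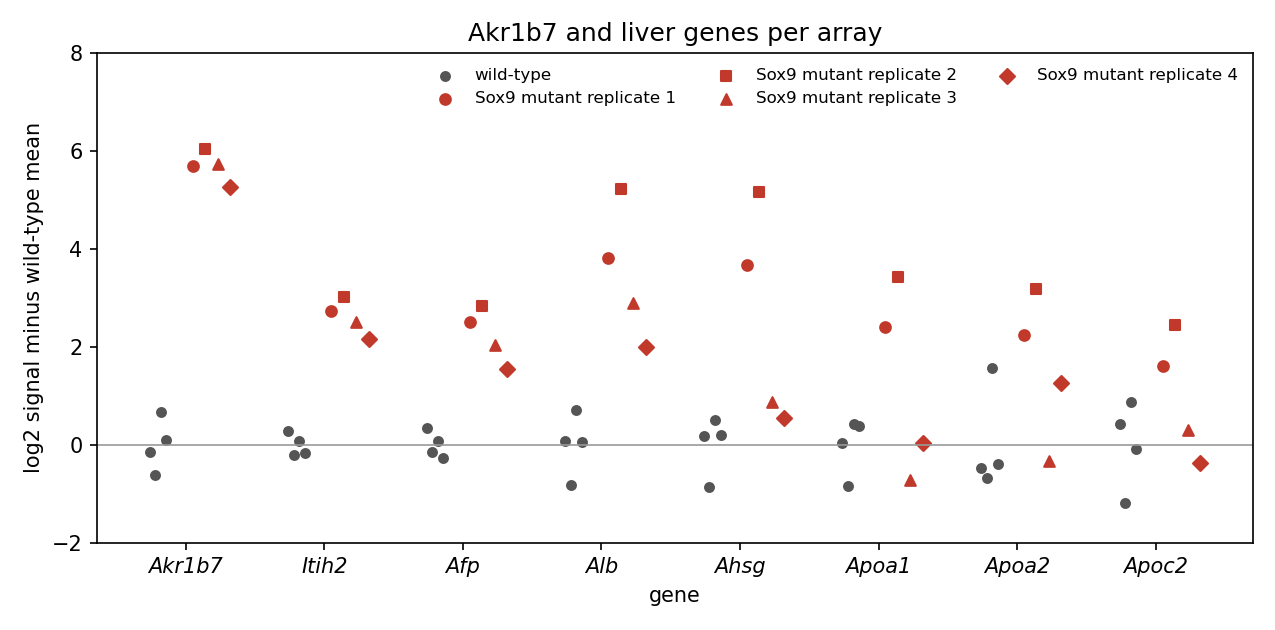
Log2 signal minus the mean of the 4 wild-type arrays (vertical axis) for Akr1b7 and 7 liver genes (horizontal axis), with 1 point per array, wild-type in grey and the 4 Sox9 mutant replicates as red circles, squares, triangles and diamonds. Akr1b7 (difference of means 5.68), Itih2 (2.60), Afp (2.23) and Alb (3.48) are higher in all 4 mutant arrays, and Ahsg, Apoa1 and Apoc2 mostly in mutant replicates 1 and 2.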

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

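The test used here was set before the data were examined, and no explanation was tested for these values. In each group of 4 arrays, the gap between the sample farthest out and its nearest neighbour was divided by the range of the group, and compared with the critical value of Dixon's test. Of 240 groups of named genes and lists, 12 exceeded it, and chance alone flags about 1 in 20 groups, or 12 here. Of the 12, 11 are given.

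Among the wild-type samples, replicate 3 stood apart for Mnx1 (0.860, with a log2 signal of -0.86 against -1.45 to -1.37 in the others) and for Cdh1 (0.970, with 3.11 against 2.82 to 2.83). Replicate 1 stood apart for Chgb (0.856, with 5.06 against 4.15 to 4.28), for Klb (0.831, with 0.067 against -0.90 to -0.73) and for the mean of the mesothelium list (0.931, with -0.26 against 0.073 to 0.098 relative to the wild-type mean). Replicate 4 stood apart for Tal1 (0.830, with 0.13 against -0.15 to -0.11) and for the mean of the Fgf receptor and response list (0.900, with -0.16 against 0.044 to 0.067).

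Among the mutant samples, replicate 2 stood apart for Sox10 (0.927, with -1.03 against -2.0 to -1.93). Replicate 4 stood apart for Col9a3 (0.894, with -1.62 against -4.05 to -3.79). Replicate 1 stood apart for the mean of the stomach and intestine list (0.936, with 0.19 against -0.30 to -0.27) and for Xist, the RNA that silences an X chromosome in females (0.952, with -5.73 against 3.11 to 3.56).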

How the results depend on the processing

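The alternatives chosen only after the data were seen were leaving out 2 arrays together, the Y-linked covariate and the other Sox9 probes; the rest were set beforehand. Neither Sox9 nor a named gene past the threshold changed sign, which leaving out arrays could not do because the groups did not overlap, and with the covariate all 994 genes kept their direction. Where no reason is given, the cause was not tested.

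The count of changed genes, 994, became 191 (13 higher, 178 lower) at an adjusted p under 0.01, 1763 (696 and 1067) at 0.1, and 534 (45 and 489) with a 2-fold minimum, as stricter or looser thresholds must change it. It was 419 (42 and 377) with no filter on dim probes, where 27828 genes were tested, 1529 (575 and 954) with slide as a random block, and 1709 (659 and 1050) with array weights. Leaving out 1 array gave 395 to 976 genes (503, 656, 494 and 395 without wild-type replicates 1 to 4, 412 and 448 without mutant replicates 1 and 2), of which 385 to 788 were among the 994, and 9.47% to 33.2% were higher. With the replicate number as a block it was 340 (27 and 313). It stayed within 1.5 times of 994 in the other planned settings, with 947 for quantile normalization, 955 for normexp, 1311 for the authors' table (851 shared), 1051 for the filter on all arrays, 994 with outlier spots kept, 909 for the mean of probes, 1292 with slide as a fixed block and 1225 with a variance trend. Without wild-type replicate 1 and mutant replicate 3, the arrays of lowest weight (0.407 and 0.313), 64 genes passed. Without mutant replicates 1 and 2, which were picked by their measured liver gene levels, 0 genes passed in limma and 2258 had an unadjusted p under 0.05. With the Y-linked level as a covariate, 2 passed and 2935 had an unadjusted p under 0.05. That level runs with genotype, so the covariate takes up part of the comparison.

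The Sox9 difference, -2.70, stayed negative in all settings. It no longer passed with no filter (-2.70, adjusted p = 0.0605), without the 2 arrays of lowest weight (-2.59, 0.101), without mutant replicates 1 and 2 (-1.91, 0.132), with the Y-linked covariate (-2.03, 0.260), or for the dimmest probe (-1.44, 0.0748). Leaving out 1 array gave -3.09 to -2.24, with adjusted p from 0.0115 to 0.0732 and the call lost without wild-type replicate 1 (0.0672), 2 (0.0525) or 4 (0.0691) or mutant replicate 1 (0.0732), against 0.00510 to 0.260 over all alternatives.

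No pairing by replicate number was seen: deviations of arrays of the same number correlated over genes at -0.35, -0.29, -0.0047 and 0.086. Wild-type and mutant arrays of the same number always lay on different slides, while those sharing a slide correlated at -0.090 to 0.57. A slide effect could therefore hide a pairing, and the check does not exclude one. With the replicate number as a block, Sox9 gave -2.70 (adjusted p = 0.0697).

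Of the 24 lists, 17 passed, 0 passed in camera with an estimated correlation (11 at an unadjusted p under 0.05, and 17 in fry), 15 to 17 on leaving out 1 array, and 14 to 17 over the alternatives other than the estimated correlation. Besides the Fgf lists, the duct list lost its call with the filter on all arrays (adjusted p = 0.0933) and with the Y-linked covariate (0.230), the Hedgehog list with that covariate (0.245), and the Bmp list without the 2 arrays of lowest weight (0.0660). Some list medians changed sign: that of the Fgf ligand list, 0.32, became -0.032 with the Y-linked covariate and that of the Fgf receptor and response list, -0.075, became 0.044 without mutant replicates 1 and 2, with the camera direction kept. That of the uncalled liver list, 0.26, became -0.20 without these 2 arrays and -0.019 with the covariate, and medians of the uncalled Notch, Wnt, p53, cell cycle and stomach lists changed sign in some settings. So did Ddx3y (-0.081) and Eif2s3y (-0.11) with the Y-linked covariate, which is made from such genes. Of the 87 named genes past the threshold besides Sox9, 42 passed on leaving out any array and 45 lost the call without some array, 38 lost it with no filter, 35 with the replicate number as a block, and 0 passed without mutant replicates 1 and 2 and 1 with the Y-linked covariate. Genes near background are limited by signal: the log2 difference of 28 named genes was at least 1.5 times smaller with normexp, whose offset shrinks changes of dim genes, of 25 in the authors' table and of 6 with the mean of probes, and 20 lower and 1 higher of the changed genes were above background on no array of their dimmer group.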

Other observations

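Of the tests of explanations given here, the count over splits of the arrays was set before its result was seen; the tests on epithelial genes, on a scale factor per array, on liver genes and on mutant replicate 4 were chosen after the results were seen.

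Stomach and intestine genes showed little change. Of 11 measured, 2 fell, none rose and 9 did not pass, with the same count when adjusted over the list alone, and the median was -0.12 (camera adjusted p = 0.154). Vil1, which encodes villin of the brush border, fell by 0.96 (adjusted p = 0.0174 in limma) and Tff3, a secreted trefoil peptide, fell by 0.82 (adjusted p = 0.0409), while with normexp Tff3 gave -0.54 and did not pass (adjusted p = 0.0679, within a range of 0.0220 to 0.189). Of the 8 fits that left out 1 array, Vil1 lost the call in 2 and Tff3 in 7. The mean shift within slides 1, 2 and 3 was 0.00098, -0.42 and -0.25, and -0.24 with slide as a block. The list passed in camera on leaving out mutant replicate 1 (median -0.22, adjusted p = 0.0330), within a range of 0.0309 to 0.831 over the alternatives. Of 18 genes of the response to dissection and heat shock, 1 rose, none fell and 17 did not pass, with the same count when adjusted over the list alone, and the median was 0.25 (camera adjusted p = 0.189). The gene was Hspa1a (0.69, adjusted p = 0.0441), which a near-identical copy, Hspa1b, makes uncertain and which lost the call in all 8 fits that left out 1 array (highest adjusted p 0.113), and the mean shift within slides was 0.18, 0.13 and 0.33, with 0.22 for slide as a block. This heat shock list passed in camera with no filter on dim probes (median 0.28, adjusted p = 0.0276), within a range of 0.0276 to 0.351 over the alternatives.

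Among progenitor factors that did not pass the threshold in limma, chosen after their values were seen, Gata4 had a difference of -0.10, Gata6 of 0.17 and Rbpj of 0.047. Sex-linked genes differed between the pools. Ddx3y, a gene of the Y chromosome, had log2 signals of -6.84, -4.86, -0.82 and -7.43 in wild-type replicates 1 to 4 and of 0.11, -0.85, -0.92 and -1.37 in mutant replicates 1 to 4. Xist had 4.75, 4.43, 3.44 and 4.52 in the wild-type and -5.73, 3.11, 3.54 and 3.56 in the mutant samples. The log2 difference was 4.23 for Ddx3y (adjusted p = 0.111), 4.32 for Eif2s3y (adjusted p = 0.117), 2.75 for Kdm5d (adjusted p = 0.125) and -3.16 for Xist (adjusted p = 0.479), so none of these genes passed. Y-linked levels were low in 3 of 4 wild-type pools and in no mutant pool, so that embryo sex ran in part with genotype and cannot be fully separated from it, and with the Y-linked level as a covariate 2 genes passed.

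The number of genes changed in limma was compared with all 35 splits of the 8 arrays into 4 and 4. Only 1 split, the real one, gave as many as 994 genes, and the highest of the others gave 2. This is the smallest share that 35 splits can give, so it argues against chance in the assignment of arrays without excluding it. The splits took no account of slide, and they cannot tell genotype from embryo sex or another difference that runs with it.

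General epithelial genes were lower in all 4 mutant samples, with a mean list shift of -1.89. Suppose a smaller share of epithelial cells were the whole cause, with other cell types in fixed proportions and all epithelial cells lost alike. The markers of other cell types would then rise alike. The shift of the neural crest list minus the mean of the mesenchyme, mesothelium, endothelium, erythroid and macrophage lists was -1.08 (SE 0.151, exact permutation p = 0.0286). The hormone list fell by less than the epithelial list, by a difference of 0.88 (SE 0.189, exact permutation p = 0.0286). This contrast takes all members of the hormone list as epithelial. Expression of some members in other cells, which was not measured, would also make its fall smaller. Both contrasts were chosen after the list shifts had been seen, so their p-values restate those shifts and add no support of their own. The values argue against that uniform change only, because unequal changes in the shares of single cell types could give both. One scale factor per array would shift all lists alike. The epithelial list fell while the same 5 lists rose, which argues against such a factor. The epithelial list minus their mean was -2.43 (SE 0.358, exact permutation p = 0.0286), and this p only restates the shifts already seen. All 15 measured neural crest genes were above background on every wild-type array, and none of them is in another list. A smaller epithelial share as part of the cause, lower expression within epithelial cells, and a change within the neural crest may each contribute, and the design separates the genotype neither from the Cre transgene nor fully from embryo sex.

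Afp, Alb and Itih2 were higher in every mutant sample. Liver tissue in the samples would keep its genes in 1 ratio. The smallest rise among the mutants as a share of the largest was 0.317 for Afp, 0.486 for Itih2 and 0.0805 for Alb (0.0560 after allowing for 2 wild-type SDs), and for 8 other liver genes raised at least 2-fold in some mutant it was 0.0115 at most, with upper bounds of up to 0.273. After the same allowance, the share of Itih2 (0.440) lay above the upper bounds of all 8 other genes, and that of Afp (0.252) above 7 of them. That of Alb lies below the highest bound. These 3 genes were picked because they rose in all 4 mutants, which favours a large share. For the 3 genes as a set, liver tissue and another source therefore cannot be told apart. Of the 20 measured liver genes, 16 were above background on every wild-type array and none is in another list.

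Mutant replicate 4 lay closest to wild-type among the mutants, with 15.7 on the first principal component and a Sox9 signal of 0.77. A candidate explanation is wild-type or unrecombined tissue in that pool, which would place every gene the same share of the way from the other mutants to wild-type. Shares of lists were computed from the mean log2 signal of each list, brought back to a linear scale. Even with such tissue they need not be equal between lists, because genes within a list change by unlike amounts. The share ran from -15.5% to 57.7% for the 9 lists that fell and from 14% to 83.3% for the 8 that rose, and with 2 SDs of the other 3 mutants allowed, shares from 19.1% to 23.2% lay inside the bounds of all 17, the neural crest list, at -15.5% (bounds -94.1% to 63.1%), included. The quartile ranges of single genes called without that array did not overlap, with 12.8% to 32.4% for 652 genes that fell and 41.9% to 69.8% for 324 that rose. These genes were picked without replicate 4, which by itself places that array nearer to wild-type, and more so where changes are small. The gap between falls and rises therefore decides nothing. The list comparison and its bounds were chosen after the shares had been seen. Such tissue and a milder effect in that pool cannot be told apart.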
